A study of Homo sapiens with 3 samples.

How the data were processed

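RNA of MTAC-P cells was profiled in 3 libraries, 1 with a control hairpin against luciferase and 2 with hairpins against BCAT1, grouped by the knockdown label and numbered by the title. The cells were grown in DMEM with 10% serum and total RNA was taken with Trizol for Illumina libraries, per the labels' protocols. The series' design text names a Genome Analyzer IIx and speaks of triplicate, while 1 and 2 libraries were analysed here. Trim Galore, TopHat, Cufflinks and the genome build hg38 were used per the submitters' processing notes, which give no role or order here. The usual roles of these tools are trimming, spliced alignment and transcript quantification. Their versions, settings, the annotation and the strand of the libraries are not given in the sources used here. The deposited values are FPKM, fragments scaled to transcript length and to the total of mapped fragments, computed by the authors for each library on its own, 1 value per RefSeq transcript and locus with a lower and an upper confidence bound and a status. FPKM corrects for transcript length and total, not for a few transcripts that take a large part of the total, and the 3 most abundant entries held 21.3%, 23.5% and 22.7% of it in the control and the libraries labelled shBCAT1 1 and shBCAT1 2.

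Each table held 56882 entries for 50337 transcript accessions. A RefSeq gene table on GRCh38.p14 named 49281 of them and GENCODE release 29 another 625, and 431 kept no gene name. FPKM was summed over the entries of a gene, alternative and unplaced sequences included (5930 entries), to give 26546 genes. The plan made beforehand had kept the transcripts of a gene apart, with summing as the alternative. This was turned round before any test because the entries were found to be transcripts, and keeping them apart is the alternative here. Genes with a status other than OK in any library were left out, 341 in all and 56 with a mean of 1 FPKM or more. The spread of a gene's value was taken from its bounds, as a root sum of squares over entries, with 2 SDs from value to bound. It is called counting error here and covers no spread between libraries. It is not counting alone, since EIF3CL had an SD of 1.50 at 0.844 FPKM in the control. In the library labelled shBCAT1 2 that gene had an SD of 0.136 at 0.422 FPKM. The square of value over SD was read as equivalent fragments. The median SD of a gene was 13.2%, 13.6% and 12.5% of its value in the 3 libraries, and relative depth was 1.03 and 1.09 times the control in the libraries labelled shBCAT1 1 and shBCAT1 2. Read totals are unknown, and values at 0 have bounds of 0, so no floor can be given for them.

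The comparison was fitted in limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), values as deposited, for genes with a mean of at least 1 FPKM, with an intensity trend and Benjamini-Hochberg adjustment. All p-values are two-sided. A log2(FPKM + 1) difference understates the change of low genes. The control has 1 library, so the spread comes from the libraries labelled shBCAT1 (1 residual degree of freedom, prior degrees of freedom 2.99) and the control is assumed to vary like them. Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with the correlation estimated from residuals as an alternative, and their medians were set against 10000 random lists matched on level in 20 bins, or on level in 5 and transcript length in 10 bins. Chance values for comparisons that share the control came from 100 simulated sets. Their noise, as in the simulated test of the fit, was the difference between the libraries labelled shBCAT1, drawn within 20 bins of level. Lengths came from GENCODE transcripts matched to the accessions, weighted by FPKM, and the length trend was removed by loess with a span of 0.5. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 built the tables and plots. Coordinates are those of the deposited tables, on hg38.

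The groups, the fit, the minimum of 1 FPKM, the 2-fold rule in both libraries, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names BCAT1 and the measured genes of branched-chain amino acid catabolism, the 12 genes in each direction with the largest smaller difference of the same sign in both libraries (past the adjusted p first, then filled from others, loci of 300 bases or more, no small RNA, antisense or uncharacterised loci), and up to 4 genes per list by the same measure. Genes named for 1 library, the comparison of each library with the control, the counts of genes with bounds apart, the removal of the length trend and the minimum of 10 equivalent fragments were chosen after the data had been seen. The values of 1 gene, and of 1 untested list of which it is a measured member, are not reported here.

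The fit was tested on simulated data with the 3889 genes tested, 200 of them changed, in 20 repeats. It recovered 9.05% of genes changed 2-fold and 50.5% of those changed 4-fold, with 13.4 false calls on average, and called 7.6 genes (0 to 27) when none was changed. Simulated lists of 30 genes shifted by -0.5 were found in 20 of 20 repeats with the preset correlation and in 0 of 20 with the estimated one, and 0 unmoved lists were called. The lists were random genes with noise drawn gene by gene, without correlation within a list or a length trend. These counts therefore cannot check the preset correlation for lists of genes that vary together. By counting error alone the per-library rule gave 1.7 lower and 1.75 higher genes on average, at most 5. Alternatives covered the pseudocount, the minimum level, the scaling, short loci, transcripts kept apart, the variance prior, the set test, the fold, the length trend and each library labelled shBCAT1 left out.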

Results

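RNA-seq libraries of MTAC-P cells, a lung cancer line derived from PC9 that is resistant to EGFR tyrosine kinase inhibitors, were compared between a control short hairpin against luciferase (1 library) and short hairpins against BCAT1 (2 libraries). BCAT1 encodes the cytosolic branched-chain aminotransferase, which moves the amino group of leucine, isoleucine and valine to 2-oxoglutarate and so makes glutamate. The labels do not say whether the libraries labelled shBCAT1 1 and shBCAT1 2 carry the same hairpin or come from separate cultures. The p-values of limma therefore rest on the spread between these libraries, which may be technical, and on a prior pooled over genes. Those of camera at the preset correlation rest on the spread of statistics across genes. A shift of the single control library shared by the genes of a list can therefore make them low. The files give FPKM per RefSeq transcript with the confidence bounds of Cufflinks and no read counts. FPKM summed to 53898 in the control, 44312 in the library labelled shBCAT1 1 and 46145 in the library labelled shBCAT1 2, and 3913, 3730 and 4076 genes reached 1 FPKM. Depth relative to the control, read from the width of the bounds, was 1.03 and 1.09 in the libraries labelled shBCAT1 1 and shBCAT1 2. Across genes, log2(FPKM + 1) correlated at 0.946 and 0.924 between the control and these libraries and at 0.942 between the libraries labelled shBCAT1, with genes not being independent replicates.

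BCAT1 itself (chromosome 12, 24810024 to 24949459, hg38) had no lower summed value in either library labelled shBCAT1. It stood at 0.213 FPKM in the control (bounds 0.129 to 0.297), at 1.05 FPKM in the library labelled shBCAT1 1 (0.835 to 1.27) and at 0.241 FPKM in the library labelled shBCAT1 2 (0.158 to 0.325). The value in the library labelled shBCAT1 1 was 4.96 times that of the control, 7.16 times the counting error of the difference, and 4.37 times that of the library labelled shBCAT1 2. The library labelled shBCAT1 2 was at 1.13 times the control, 0.483 times the counting error. These are sums over 5 RefSeq transcripts, and the transcript that held the control's value, at 0.213 FPKM (bounds 0.134 to 0.292), was at 0.445 (0.304 to 0.587) in the library labelled shBCAT1 1, with 0.61 on a further transcript, and near 0 in the library labelled shBCAT1 2 (upper bound 0.0135), whose value lay on another transcript at 0.241 FPKM (0.162 to 0.321). The mean of the libraries labelled shBCAT1 was 0.648 ± 0.575 FPKM (SD, n = 2), and the fitted log2(FPKM + 1) difference from the control was 0.40 ± 0.43 (SE), with a limma adjusted p of 0.863 among 16442 genes tested without a filter. The target gene thus goes against the label of the library labelled shBCAT1 1 and its summed value shows no reduction detectable at this depth in the other, so each direction given here is between libraries as labelled, not between cells shown to have less BCAT1. These bounds cover no spread between libraries, and the level is below the minimum of 1 FPKM used for the tests across genes.

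**Figure D1:**
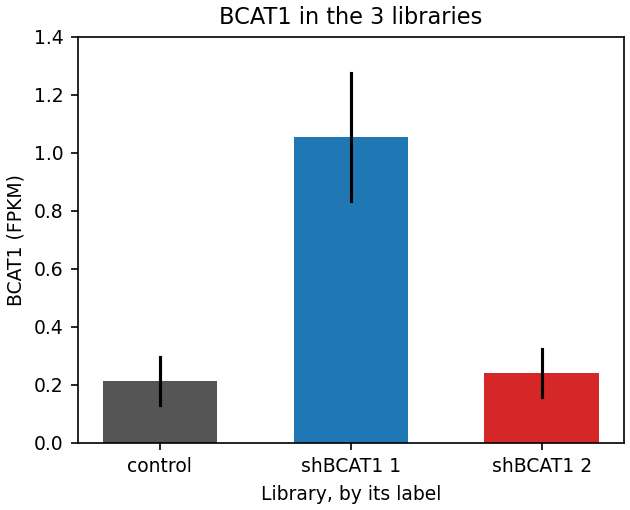
FPKM of BCAT1, summed over its transcripts, in each of the 3 libraries. Error bars are 2 SDs, combined over the transcripts from the bounds that Cufflinks gave. The library labelled shBCAT1 1 sits at 1.05 FPKM, above the control at 0.213 and the library labelled shBCAT1 2 at 0.241.

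The comparison of the libraries labelled shBCAT1 with the control asks which transcripts change when BCAT1 is targeted. Genes of several small proteins had lower values in both. COX17 (chromosome 3, 119669525 to 119677396), the copper chaperone of cytochrome c oxidase, was at 17.2 FPKM in the control and 8.67 ± 0.14 in the libraries labelled shBCAT1 (SD, n = 2), a log2(FPKM + 1) difference of -0.91 ± 0.19 (SE). HINT2, a mitochondrial nucleotide hydrolase, was at 4.14 against 1.47 ± 0.35 FPKM, and LAMTOR4, a subunit of the Ragulator complex that anchors mTORC1 signalling to the lysosome, at 13.8 against 7.12 ± 0.17. TMEM258, a subunit of the oligosaccharyltransferase complex, was at 27.7 against 14.3 ± 1.2 FPKM and the mitochondrial ribosomal protein gene MRPL53 at 4.7 against 1.75 ± 0.75. MIX23, STX8, H2BC4, SNHG8, MGST2 and RPS29 were lower in both libraries as well, RPS29 at 262 against 136 ± 19 FPKM. None of these genes passed the limma test, with an adjusted p of 0.797. Their transcripts were short, from 300.3 bases for RPS29 to 1162 for MRPL53, and short transcripts were lower in general in both libraries. The bounds of H2BC4 and SNHG8 overlapped those of the control in both libraries. Those of HINT2, MRPL53 and MGST2 overlapped them in the library labelled shBCAT1 1 and those of STX8 in the library labelled shBCAT1 2.

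Among genes with higher values in both libraries, the transcription factor gene ATF7 (chromosome 12, 53507856 to 53626415) was at 0.817 FPKM in the control and 1.89 ± 0.035 in the libraries labelled shBCAT1 (SD, n = 2). TNIK, a kinase that acts in Wnt signalling, was at 1.11 against 2.4 ± 0.26 FPKM, GABARAPL2, a member of the ATG8 family of autophagy proteins, at 1.08 against 2.68 ± 0.77, and the zinc finger gene ZFAND3 at 1.1 against 2.1 ± 0.12. Their log2(FPKM + 1) differences were 0.67, 0.68, 0.81 and 0.56, each with an adjusted p of 0.797 from limma. The bounds of ATF7 and TNIK overlapped those of the control in both libraries, and those of GABARAPL2 in the library labelled shBCAT1 2. Those of ZFAND3 lay apart in both. The other genes named by the same rule were the histone gene H2BC17 and members of families with near-identical copies, NPIPA5, NPIPB3, NPIPB4, PDXDC2P-NPIPB14P, AGAP4, SPDYE2B and SPDYE7P, whose values are uncertain because reads shared between copies can be split either way. NPIPB3 was at 8.96 FPKM in the control and 15 ± 1.3 in the libraries labelled shBCAT1.

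Of 3889 genes tested, 14 fell and 0 rose at an adjusted p of 0.05 by limma with a trend, and 193 were lower and 25 higher at an unadjusted p under 0.05. The latter counts were 103 and 72 with median-of-ratios scaling, 80 and 87 with quantile normalization and 74 and 95 with the length trend removed. The genes that fell were read at 0 in both libraries labelled shBCAT1, most of them small RNA genes: SNORA6, SNORA24, SNORA38B, SNORA63, SNORA71D, SNORA84, SNORD50A, SNORD97, MIR6087, MIR6803, MIR8086, SNHG25 and, uncertain for their near-identical copies, SNAR-A12 and SNAR-B1. SNHG25, a host gene of small nucleolar RNAs (chromosome 17, 64145970 to 64146309), was at 18.5 FPKM in the control and listed at 0 in both libraries, with a limma adjusted p of 0.00937. Its transcript had 106 bases in a locus of 340, and its bounds in the control were as wide as those of 1 fragment. The other 13 span under 300 bases, and the bounds of the 14 genes in the control were as wide as those of a median of 1.00 fragment. With no filter on level limma called 0 of 16442 genes, and without loci under 300 bases 1, SNHG25. Of 3629 protein-coding genes, 0 passed, with a smallest adjusted p of 0.797. When unchanged libraries were simulated, limma called 7.6 genes on average (0 to 27), and a count of 14 lies within that range. The simulated noise came from the difference between the libraries labelled shBCAT1 and holds any real difference between them, so the range may be too wide.

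At 2-fold or more on the log2(FPKM + 1) scale in both libraries, 2 genes were higher, RNA5S9 and SCARNA16, and 16 were lower, beside 18.9 and 18.8 in simulated libraries with no change that share the control. Among loci of 300 bases or more these counts were 0 and 1. The differences of the libraries labelled shBCAT1 from the shared control correlated across genes at 0.609, beside 0.499 in simulation (0.419 to 0.576). Their covariance was 0.150 beside 0.0991 simulated (0.0746 to 0.123), a difference of 0.0509, while resampling genes moved the covariance between 0.0990 and 0.213. The same sign in both was found for 69.3% of genes beside 66.4% simulated (64.6% to 68.1%). The correlation, the covariance and the same-sign share lay above their simulated ranges, the count of lower genes within its range (10 to 30) and the count of higher genes below it (9 to 30). The covariance itself was 0.0622 without loci under 300 bases, 0.0599 with a pseudocount of 5 and 0.0373 at a minimum of 10 equivalent fragments, with no simulation beside these. With 1 control library the control could not be split, and part of any excess may come from it. The simulated values hold any real difference between the libraries labelled shBCAT1, from which their noise was drawn.

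Cytosolic ribosomal protein genes, which share reads with many processed pseudogenes, were lower as a group in both libraries labelled shBCAT1. Of 39 measured, 38 were lower in both, with a median log2(FPKM + 1) difference of -0.50 beside -0.06 for all genes. RPS21 was at 214 FPKM in the control and 131 ± 4.9 in the libraries labelled shBCAT1 (SD, n = 2), RPS14 at 191 against 119 ± 2.8, RPS25 at 82.6 against 51.8 ± 4.9 and RPL18 at 67.9 against 44.6 ± 0.26. Nuclear-encoded genes of oxidative phosphorylation had a median of -0.36, with 25 of 29 measured lower in both. UQCRFS1, the Rieske iron-sulfur subunit of complex III, was at 7.29 against 3.66 ± 0.36 FPKM, and COX7C and COX6A1, subunits of cytochrome c oxidase, were at 59.1 against 36.1 ± 3.4 and 43.5 against 27.1 ± 1.1. By camera with a preset correlation of 0.01 the ribosomal list had an adjusted p of 5.14e-16 and the oxidative phosphorylation list of 0.000108. Both had an adjusted p = 0.988 by camera with an estimated correlation (unadjusted p 0.0709 and 0.124). The estimates were 0.0067 and -0.0049. With 1 residual degree of freedom they reflect only how many genes were higher or lower in 1 library labelled shBCAT1 than in the other. They therefore cannot check the preset 0.01. In simulation the test with an estimated correlation found shifted lists in 0 of 20 repeats, so it cannot decide here. The median of the ribosomal list lay at percentile 0.325 of 10000 random lists of the same level and at percentile 0 of lists of the same level and transcript length. For oxidative phosphorylation these were 0.0700 and 3.89. The ribosomal call was lost with quantile normalization (median -0.09, adjusted p 0.0737), and that of oxidative phosphorylation at a minimum mean of 5 FPKM (adjusted p 0.219), where its median was -0.34 beside -0.22 for all genes.

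Glutathione genes and NRF2 targets, which handle oxidants and conjugate xenobiotics, were also lower. For glutathione synthesis and use, 13 of 15 measured genes were lower in both libraries, with a median of -0.37, among them GPX4, which reduces lipid peroxides, at 48.3 FPKM in the control and 33.1 ± 4.4 in the libraries labelled shBCAT1 (SD, n = 2). GSTM2, a glutathione transferase with close paralogs and so uncertain, was at 2.36 against 0.849 ± 0.51 FPKM. Of 21 NRF2 targets, 16 were lower and 2 higher in both, with a median of -0.21. The aldo-keto reductase genes AKR1C1 and AKR1C3, which are similar in sequence, were at 52.9 against 27.7 ± 12 and 29.3 against 19.2 ± 0.11 FPKM, and thioredoxin (TXN) at 42.4 against 27.7 ± 2.2. By camera with the preset correlation the adjusted p was 0.00301 for the glutathione list and 0.0188 for NRF2 targets. For each the adjusted p = 0.988 with the correlation estimated, at 0.314 and 0.143, an option that missed shifted lists in simulation. Their percentiles were 0.440 and 42.5 among random lists of the same level, and 2.30 and 3.83 among lists of the same level and length. In single libraries the percentiles on level and length were 15.5 for glutathione and 41.1 for NRF2 targets in the library labelled shBCAT1 1, and 0.165 and 0.115 in the library labelled shBCAT1 2. The NRF2 list's median over both was not low for genes of its level (percentile 42.5), and its call was lost with median-of-ratios scaling (adjusted p 0.0875). Both calls were lost with quantile normalization (0.0592 for glutathione and 0.534 for NRF2 targets) and at a minimum mean of 5 FPKM (0.334 and 0.418), and that of NRF2 targets with transcripts kept apart (0.539).

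Genes of branched-chain amino acid catabolism other than BCAT1 showed no common direction. Of 25 list members, 4 were measured above the minimum, too few for the list test. BCAT2, the mitochondrial aminotransferase, was at 4.27 FPKM in the control and 2.31 ± 1.1 in the libraries labelled shBCAT1 (SD, n = 2). BCKDHA, a subunit of the branched-chain ketoacid dehydrogenase, was at 1.69 against 1.96 ± 0.092 FPKM, a difference of 0.13 that became -0.21 with transcripts kept apart, and ECHS1, an enoyl-CoA hydratase, at 8.32 against 6.4 ± 0.51. HSD17B10, which acts in isoleucine breakdown, was at 5.77 against 5.37 ± 0.68 FPKM, a difference of -0.09 that became 0.06 with quantile normalization. Adjusted p by limma was 0.797 for BCAT2, 0.877 for BCKDHA, 0.804 for ECHS1 and 0.932 for HSD17B10.

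Of 44 gene lists fixed beforehand, 27 had at least 5 measured genes and were tested, and 4 passed, all lower. In every list 0 genes passed adjusted over the list alone, and 0 passed when adjusted over all genes tested, by limma. Lists that did not pass by camera with the preset correlation included ATF4 targets of the amino acid response (18 genes, median 0.04, adjusted p 0.539), H3K9 methyltransferases (median 0.14, 0.469), DNA methylation machinery (0.11, 0.539), fatty acid synthesis (0.09, 0.388), other antioxidant enzymes (-0.23, 0.539, but 0.0215 at a minimum of 10 equivalent fragments), antigen presentation (-0.24, 0.548), mTORC1 amino acid sensing (-0.24, 0.791) and glutamate metabolism (0.02, 0.791). Medians of cholesterol synthesis, apoptosis regulators, ERK output, epithelial genes, stemness genes and S phase genes were -0.09, -0.09, -0.04, -0.05, 0.04 and -0.02, each with an adjusted p of 0.791, as was autophagy and lysosome at -0.15. The unfolded protein response (-0.00, 0.811), G2 and M phase (-0.15, 0.811), TCA cycle (-0.05, 0.884), glycolysis (-0.08, 0.950), heat shock (-0.13, 0.950) and NF-kB genes (-0.09, 0.950) did not pass either. The checks of RNA quality gave -0.16 for histone genes without poly(A) tails (adjusted p 0.539) and -0.02 for nuclear long non-coding RNAs (0.811). The latter list does not hold only such RNAs, since RN7SL2, annotated as scRNA and 300 bases long, is a member. The signs of the median, the mean and the test differ in 7 lists: the unfolded protein response, S phase genes, ERK output, epithelial genes, stemness genes, NF-kB genes and nuclear long non-coding RNAs. The test sets a list's moderated statistics against those of all other genes, whose mean difference was below 0 (-0.09 over all genes).

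The 17 lists with fewer than 5 measured genes gave values only. Of the EGFR family and its ligands 3 were measured, EGFR at 4.16 FPKM in the control and 5.87 ± 0.5 in the libraries labelled shBCAT1 (SD, n = 2), the EGFR ligand AREG at 2.04 against 0.871 ± 0.3, and ERRFI1, a feedback inhibitor of EGFR, at 0.636 against 1.21 ± 0.74. Amino acid transporters had 3 measured, with a median of -0.07 and SLC7A5, a leucine transporter, at 6.05 against 9.2 ± 3.4 FPKM. p53 targets (3 measured), type I interferon genes (4), 2-oxoglutarate dioxygenases (4), drug efflux transporters (2) and bypass receptors (2) had medians of 0.12, -0.25, 0.20, 0.09 and 0.22. Hypoxia and lung lineage lists had 1 measured gene each, at 0.07 and 0.28. Markers of other cell types were nearly all below 1 FPKM, with 1 measured gene each for fibroblasts, leukocytes and HEK or neural cells, at 0.38, 0.04 and -0.06, and 0 for endothelial, erythroid and liver cells. Genes encoded by the mitochondrial genome had 0 entries.

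**Figure D2:**
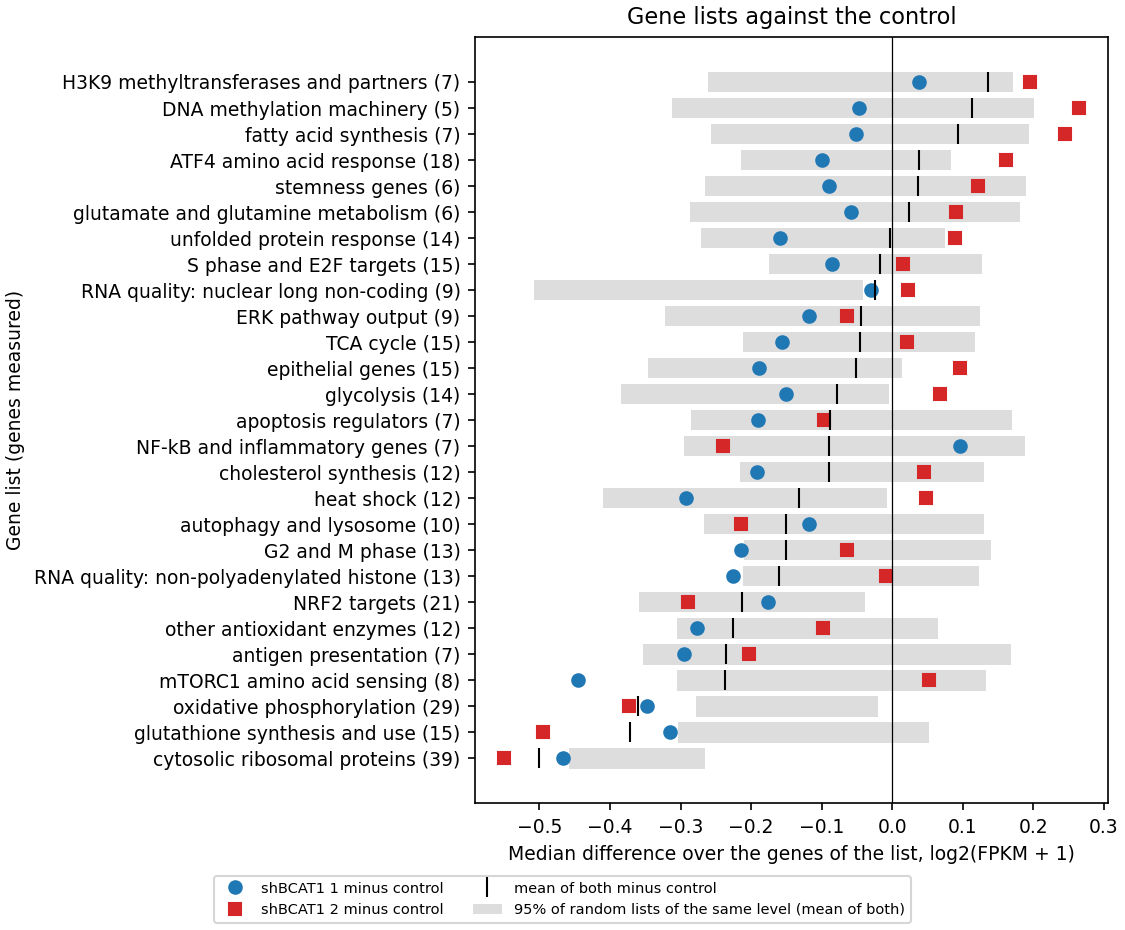
Median log2(FPKM + 1) difference from the control of each tested gene list, for the library labelled shBCAT1 1 (circles), the library labelled shBCAT1 2 (squares) and their mean (ticks), with 95% of random lists of the same level as bars. The 39 cytosolic ribosomal protein genes lie lowest, at -0.47 and -0.55.

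Differences from the control followed transcript length in both libraries labelled shBCAT1. Across 3801 genes (97.7%) with a length, Spearman's rho between length and difference was 0.406 and 0.411, and 0.149 for the difference between the libraries labelled shBCAT1. The 198 genes with transcripts of 300 to 700 bases had median differences of -0.41 and -0.47, and the 306 genes over 5000 bases of 0.04 and 0.17. Genes whose bounds lay apart from those of the control in both libraries numbered 162 lower and 49 higher (76.8% lower), and 104 and 97 (51.7% lower) after median-of-ratios scaling, which moved the median difference of the library labelled shBCAT1 1 from -0.12 to -0.00. Among transcripts under 1000 bases, 77 genes of 601 were lower and 0 higher in this way, and over 1000 bases 82 and 45 of 3200. With the length trend removed, the lists had medians of -0.25 for ribosomal proteins (adjusted p 7.82e-07 by camera), -0.09 for oxidative phosphorylation (0.0335), -0.26 for glutathione (0.0335) and -0.17 for NRF2 targets (0.0108). The list named nuclear long non-coding RNAs, with a median length of 333 bases, passed as well, at 0.36 (2.77e-05). Its median was -0.02 with the trend in place.

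**Figure D3:**
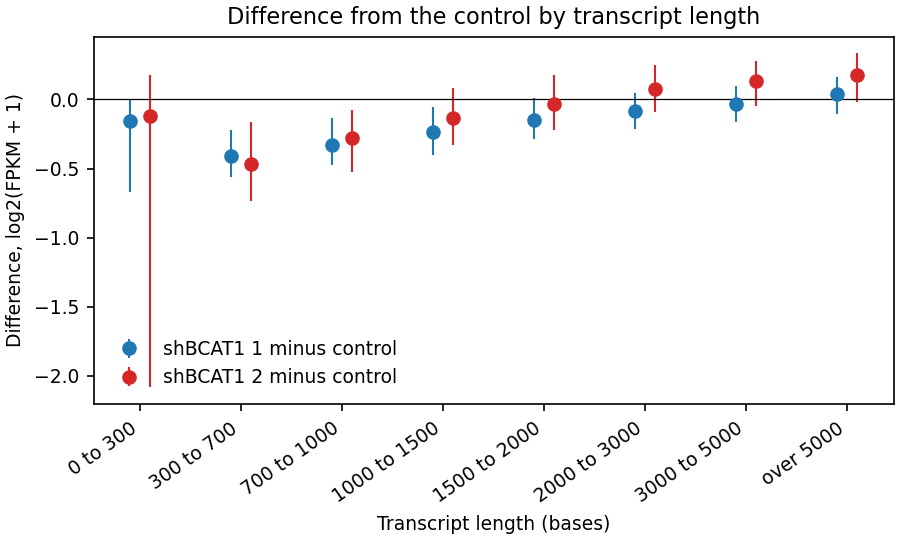
Median log2(FPKM + 1) difference from the control in classes of transcript length, for the library labelled shBCAT1 1 and the library labelled shBCAT1 2, with quartiles. In transcripts of 300 to 700 bases the medians were -0.41 and -0.47, and over 5000 bases 0.04 and 0.17.

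Because BCAT1 differed between the libraries labelled shBCAT1, each was also set against the control on its own, with no replicate and no p-value. In the library labelled shBCAT1 2, a few abundant transcripts were far lower than in both other libraries. SAA1, an acute-phase serum amyloid (chromosome 11, 18266261 to 18269976), was at 44.4 FPKM in the control, 42.4 in the library labelled shBCAT1 1 and 0.186 in the library labelled shBCAT1 2 (bounds 0 to 0.737). S100A9, a subunit of calprotectin, was at 45.8, 38.2 and 0.815 FPKM, the elastase inhibitor PI3 at 58.4, 49.4 and 2.26, and LCN2, which binds iron-carrying siderophores, at 57.8, 52.4 and 8.87. S100A8, the partner of S100A9, was at 2.49 and 2.62 FPKM and listed at 0 in the library labelled shBCAT1 2, and SAA2, close in sequence to SAA1 and so uncertain, at 3.78, 4.70 and 0. S100A4 was at 34.6, 23.0 and 10.2 FPKM and the protease inhibitor SLPI at 26.5, 16.1 and 9.15.

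Higher in the library labelled shBCAT1 2 were OLFML3, a secreted olfactomedin-like protein, at 1.63 FPKM in the control, 1.68 in the library labelled shBCAT1 1 and 7.28 in the library labelled shBCAT1 2, and MSN, which links actin to the membrane, at 1.61, 1.11 and 5.80. The imprinted non-coding RNA H19 was at 0.835, 0.782 and 4.24 FPKM, and the alkaline phosphatase gene ALPP, uncertain for its close paralogs, at 2.35, 2.27 and 7.39. By a rule of 2-fold on the log2(FPKM + 1) scale with bounds apart and a locus of 300 bases or more, 11 genes were higher and 33 lower in this library than in the control. The library labelled shBCAT1 1 had 1 higher, GABARAPL2, and 6 lower, among them PTRHD1, RBIS, TRIAP1 and SLC39A4, the last at 15.3 FPKM in the control and 6.44. No gene was shared in either direction (0 higher and 0 lower), and with 0.00283 and 0.0509 for independent lists the overlap says nothing on whether the libraries differ. With a pseudocount of 0.1 the counts were 43 higher and 61 lower in the library labelled shBCAT1 2 and 5 and 27 in the library labelled shBCAT1 1, and with 5 they were 0 and 9, and 0 and 0. The rule was chosen after the values were seen, and of the genes in the library labelled shBCAT1 2, 8 higher and 10 lower were apart from the library labelled shBCAT1 1 as well.

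**Figure D4:**
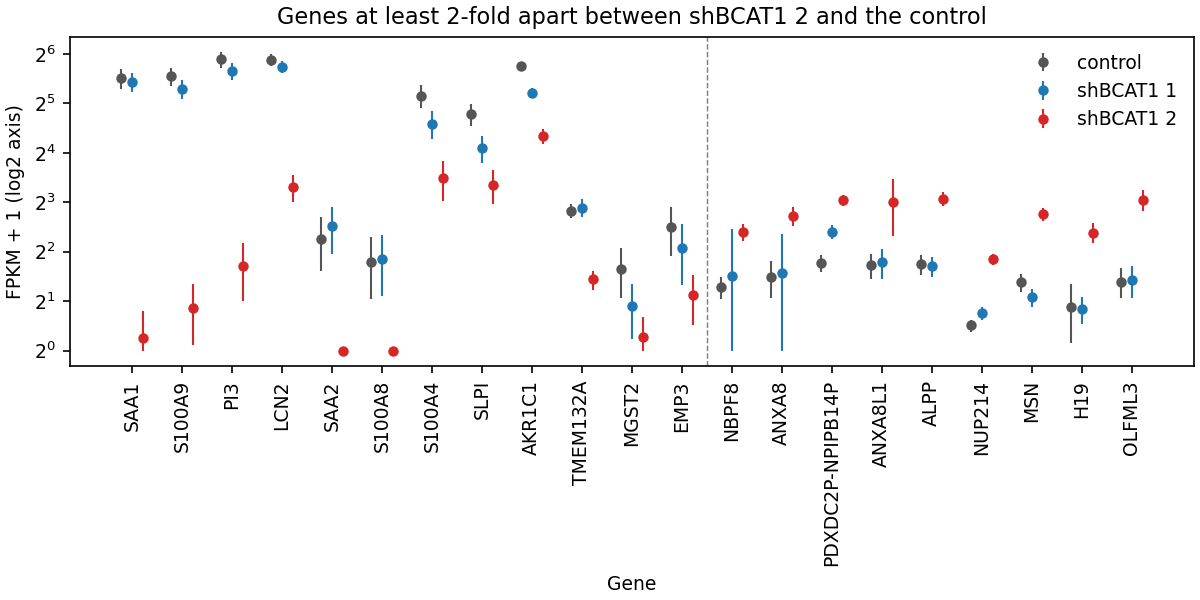
FPKM + 1 on a log2 axis in the 3 libraries for 12 lower and 9 higher genes in the library labelled shBCAT1 2 against the control, with 2 SDs of the Cufflinks interval as error bars and a dashed line between lower and higher genes. SAA1 stands at 44.4 and 42.4 FPKM in the control and the library labelled shBCAT1 1 and at 0.186 in the library labelled shBCAT1 2.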

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

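The removal of the length trend, the minimum of 10 equivalent fragments and all alternatives for single libraries were chosen only after the results were seen, and the others were planned. Of the alternative values, 1051 kept their direction and side of the threshold or moved by less than the spread. Counts were held to be kept when within a set fold of the main count. Among the 1051, 655 were for named genes and 346 for gene lists, most of them with no call to lose. Another 85 values moved further, 25 reversed, 14 lost a call and 2 gained a call. No paired analysis was possible because the control has 1 library and the groups share 1 replicate number. With 1 library against 1, after leaving out a library labelled shBCAT1, limma has no residual degrees of freedom, so counts past the adjusted p and list tests have no value. BCAT1 has none with a minimum mean of 5 FPKM or under the variance priors, being below the minimum, and short loci do not touch it. Depth limits low genes most, the median SD being 13.2% in the control. Except where fewer genes or loci were tested, the cause was not tested for any value given here.

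Against 14 genes lower at the adjusted p, limma called 0 with no filter, 8 at a mean of 5 FPKM, 1 without loci under 300 bases, 0 with transcripts kept apart and 0 at 10 equivalent fragments. Beside 0 higher, it called 1 with pseudocount 0.1, 2 with robust priors and 2 with the length trend removed. At 2-fold in both libraries, lower genes (16) became 10 at a mean of 5 FPKM, 1 without short loci, 61 with transcripts apart, 0 at 10 equivalent fragments and 80 at 1.5-fold. Higher genes (2) became 9 with pseudocount 0.1, 1 with 5, 1 at a mean of 5 FPKM, 0 without short loci, 45 with transcripts apart, 5 without the length trend, 0 at 10 equivalent fragments and 14 at 1.5-fold. Leaving out a library labelled shBCAT1 gave 27 to 64 lower and 14 to 23 higher. The covariance of the 2 shBCAT1 fold changes (0.150) was 0.340 with pseudocount 0.1, 0.0599 with 5, 0.0458 with no filter, 0.334 at a mean of 5 FPKM, 0.0622 without short loci, 0.243 with transcripts apart and 0.0373 at 10 equivalent fragments. The BCAT1 difference was 1.01 with pseudocount 0.1. Lists past the threshold (4) were 1 at a mean of 5 FPKM, 1 with quantile normalization and 0 with an estimated correlation, and other antioxidant enzymes gained a call at 10 equivalent fragments (-0.27, adjusted p 0.0215), as nuclear long non-coding RNAs did with the length trend removed (0.36, 2.77e-05). In the library labelled shBCAT1 1 the per-library rule gave 27 lower and 5 higher with pseudocount 0.1 and 0 and 0 with 5, and in the library labelled shBCAT1 2 61 and 43, and 9 and 0.

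Some lists, none past the threshold, moved to the other side of the mean of all genes in camera, with the median given here. For the genes HSD17B10 and BCKDHA the value is the difference fitted by limma, which changed sign. With no filter these were glycolysis at 0.018, the ERK list at -0.045, NF-kB at -0.081, nuclear long non-coding RNAs at -0.000256 and the unfolded protein response at -0.00254. At a mean of 5 FPKM glycolysis was at -0.090 and heat shock at -0.167. Glycolysis was at 0.0042 with median-of-ratios scaling and at 0.10 with quantile normalization, where NF-kB was at -0.075, heat shock at 0.140 and HSD17B10 at 0.059. Without short loci NF-kB was at -0.089. With transcripts apart, cholesterol synthesis was at -0.133, autophagy at 0.053, heat shock at -0.039 and BCKDHA at -0.207. With the length trend removed, E2F targets were at 0.023, stemness genes at -0.017, NF-kB at -0.125, histones at 0.201 and HSD17B10 at 0.177. At 10 equivalent fragments the unfolded protein response was at 0.0065, epithelial genes at -0.023 and NF-kB at -0.092. Among the 4 lists that passed, calls lost outside the estimated correlation were ribosomal proteins with quantile normalization (-0.09, adjusted p 0.0737), glutathione with quantile normalization (-0.14, 0.0592) and at a mean of 5 FPKM (-0.39, 0.334), oxidative phosphorylation at a mean of 5 FPKM (-0.34, 0.219), and NRF2 targets in these settings (-0.03, 0.534, and -0.31, 0.418), with median-of-ratios scaling (-0.16, 0.0875) and with transcripts apart (-0.21, 0.539). At a mean of 5 FPKM the median of all genes was -0.22. SNHG25 lost its call with no filter (adjusted p 0.592) and with transcripts apart (0.144).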

Other observations

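The tests in this part were chosen only after the results they bear on were seen, except the list test with an estimated correlation and the count of genes past the adjusted p, which were planned. The library labelled shBCAT1 2 differed from the library labelled shBCAT1 1 in genes of the amino acid response. Of 18 measured ATF4 targets, 17 were higher in the library labelled shBCAT1 2, with a median log2(FPKM + 1) difference of 0.36, above 99.98% of random lists of the same level and 99.96% of lists of the same level and length. PHGDH, the first enzyme of serine synthesis, was at 6.53 FPKM in the control, 6.69 in the library labelled shBCAT1 1 and 11.7 in the library labelled shBCAT1 2 (bounds 10.5 to 13.0), and the leucine transporter SLC7A5 at 6.05, 6.79 and 11.6. The alanyl-tRNA synthetase gene AARS1 was at 2.54, 2.61 and 4.29 FPKM, and DDIT4, an inhibitor of mTORC1 that is on the list but below the minimum and so outside the 18, at 0.515, 0.5 and 1.46. For other members the library labelled shBCAT1 1 was the low one, as for TRIB3 at 2.69, 1.55 and 2.80 FPKM, GARS1 at 2.30, 1.44 and 2.49 and WARS1 at 1.25, 0.819 and 1.18, and 13 of the 18 were lower in it than in the control. In the library labelled shBCAT1 2 against the control the same list had a median of 0.16, at percentile 95.5 of lists of the same level.

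Most measured NF-kB and inflammatory genes went the other way. Of 7 measured, 5 were lower and 2 higher in the library labelled shBCAT1 2 than in the library labelled shBCAT1 1, with a median difference of -0.33 at percentile 0.0400 of lists of the same level, and of -0.24 against the control, at percentile 5.16. NFKBIA, which encodes the NF-kB inhibitor and is itself an NF-kB target, was at 2.92 FPKM in the control, 3.45 in the library labelled shBCAT1 1 and 0.537 in the library labelled shBCAT1 2. The higher genes were NFKB2 at 1.59, 1.81 and 2.15 FPKM and the cytokine gene LIF at 2.95, 2.86 and 4.88. ICAM1, an adhesion receptor on the list but below the minimum and so outside the 7, was at 1.11, 1.06 and 0.441 FPKM. Outside the list, and chosen after their values were seen, the complement genes C3 and CFB were at 1.65, 1.81 and 0.570 and at 1.23, 1.68 and 0.428 FPKM, and INHBA, a subunit of activin, at 4.52, 3.4 and 1.39. All 12 measured heat shock genes were higher in the library labelled shBCAT1 2 than in the library labelled shBCAT1 1, with a median of 0.24 at percentile 97.6 of lists of the same level and 92.6 of lists of the same level and length, and 7 of the 12 were higher than in the control. The 15 glutathione genes had a median of -0.26 at percentile 0.01. These percentiles describe single libraries and have no replicate check.

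BCAT1 was higher in the library labelled shBCAT1 1 than in the control. Counting error is argued against by a difference of 7.16 times that error, and a trend over length or a scaling difference by a log2 ratio of 2.31 above all other genes in its class of 294 of like length and fragments (percentile 99.7). Exchanged labels of the control and the library labelled shBCAT1 1 stay open, since the control and the library labelled shBCAT1 2 differed by 0.483 times the counting error, as an exchange would need. Across all genes the values do not run as exchanged, with the lowest correlation between the control and the library labelled shBCAT1 2 (0.924). The rho with length was 0.411 between these and 0.149 between the libraries labelled shBCAT1. The correlations do not run as labelled either, being highest between the control and the library labelled shBCAT1 1 (0.946, beside 0.942 between the libraries labelled shBCAT1). Neither measure has a replicate spread to be judged by. A hairpin without effect on the transcript and a difference between cultures stay open as well, untested.

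Of the 4 gene lists lower in both libraries labelled shBCAT1, those of ribosomal proteins, oxidative phosphorylation and glutathione hold many short transcripts. Their median lengths were 980, 1039 and 1023 bases, beside 1940 for NRF2 targets. For cytosolic ribosomal proteins, the length trend as the whole cause is argued against by percentile 0 among lists of the same level and length. Their median with the trend removed was -0.25 (camera adjusted p 7.82e-07). For glutathione genes, NRF2 targets and oxidative phosphorylation the medians with the trend removed, -0.26, -0.17 and -0.09, passed camera too (0.0335, 0.0108 and 0.0335). The list named nuclear long non-coding RNAs, a check that did not pass with the trend in place, also passed with it removed (0.36, 2.77e-05). Passing camera after the removal therefore cannot decide alone. The trend stays open for NRF2 targets and oxidative phosphorylation, whose percentiles of 3.825 and 3.885 lie above the limit of 2.5. It stays open for glutathione genes as well, whose percentile of 2.295 lies below that limit but within 2 standard errors over a draw of 10000 lists. A general fall of abundant genes stays open for NRF2 targets, at percentile 42.5 of lists matched on level alone. At a mean of 5 FPKM the median of all genes was -0.22. Ribosomal proteins, oxidative phosphorylation and glutathione lay at 0.325, 0.0700 and 0.440, which counts against level as the whole cause. The ribosomal median of -0.50 lay near the range of such lists, -0.458 to -0.266. Quantile normalization, which gives all libraries the same distribution of values, took the ribosomal median to -0.09 (camera adjusted p 0.0737) and that of glutathione to -0.14 (0.0592). Level therefore stays open as a large part of the cause for these lists. Oxidative phosphorylation kept its call in that setting. Level and length together stay open for all 4, since that match held level in only 5 bins. A chance difference of the single control library stays open for all 4. The adjusted p by camera was 0.988 under an estimated correlation, a test that also missed shifted lists in simulation. An effect of the hairpins against BCAT1 stays open too, with the target gene not lower.

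Of the 33 genes lower in the library labelled shBCAT1 2 than in the control, with SAA1 and S100A9 in front, 16 lay below the control beyond the limit for all genes tested (-4.36 errors), which argues against counting error for these and leaves it open gene by gene for the other 17, though simulated counting error alone gave 1.7 such genes on average and at most 5. With the length trend between the libraries labelled shBCAT1 removed, 12 lay beyond that limit below the library labelled shBCAT1 1, beside 11 before. This removal was small for the 33 genes (median -0.0041). The library labelled shBCAT1 1 followed length against the control too (rho 0.406), so the length trend is argued against for these 12. The trend stays open gene by gene for the other 21, which lay within that limit. With the trend removed from each library 17 of the 33 were still 2-fold lower than the control, and the median went from -1.28 to -1.0. Leukocytes in the other libraries, a source of S100A8 and S100A9, are argued against because 1 of 16 leukocyte genes reached 1 FPKM in the control, CD68 at 3.42, 3.51 and 3.6, with 10 listed at 0 and LYZ at 0.173 FPKM. Differences of hairpin and culture stay open, and no biological explanation was tested.

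The 3 libraries can be split in 3 ways into 1 and 2, too few for a share under 0.05. Limma called 14 genes with the control alone, and at most 18 with another library alone, so 2 of the 3 splits gave as many. With at least 10 equivalent fragments it called 0 of 7410 genes with the control alone, 1 with the library labelled shBCAT1 1 alone and 165 with the library labelled shBCAT1 2 alone (55 lower and 110 higher in it). At an unadjusted p under 0.05 the counts at that minimum were 394, 170 and 857. The minimum was chosen after the data were seen and has no simulated count beside it, and at 1 FPKM the counts past the adjusted p were 14, 7 and 18. Other values part the control from both libraries labelled shBCAT1, such as the relation to transcript length (rho 0.406 and 0.411 against the control, 0.149 between them).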
